A study of Mus musculus with 30 samples.

How the data were processed

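RNA from dorsal root ganglia (DRG) and hind paw of female and male C57BL/6J mice was sequenced in 30 libraries, 10 groups of 3, after injection of prolactin (PRL) or vehicle (Veh) into the paw. Per the labels' protocols, 500 ng of RNA went into each library, rRNA was removed with a KAPA RiboErase kit or mRNA was selected with a TruSeq kit (the PRL_Sh groups), and single reads of 50 nt were sequenced. The submitters' processing notes name bcl2fastq, TopHat2 and HTSeq and the mouse assembly mm9; the versions, the HTSeq mode and the strand setting are not given in the sources used here. The values are raw read counts per gene, as deposited, with 22609 genes and 5 summary lines per library. Each library's group was taken from its label. The sex of each library was checked with Xist and 4 Y-linked genes. The tissue of the rRNA-depleted libraries, but not of PRL_Sh, was checked with Scn10a, Calca, Krt5 and Krt10. Gene symbols are those of the files. Of these, 20043 were current in the reference (GRCm38.p6, used for names and neighbours only), 2327 were older names with a single match and 239 had no match.

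Counts were tested with edgeR 4.0.16 in R 4.3.3. In each tissue the 12 rRNA-depleted libraries were fitted together with a mean for each group. Genes passed filterByExpr with its defaults, libraries were scaled by TMM, and the quasi-likelihood F test was adjusted by Benjamini and Hochberg with a threshold of 0.05. Contrasts were PRL against Veh in each sex, their average, their difference, and female against male Veh. PRL_Sh was compared with PRL of the same sex and tissue in a fit of 6 libraries. Comparisons, gene lists, the rule for named genes and most alternatives were set before the data were examined. Standard errors come from the edgeR fit, and levels are CPM, normalised by TMM, given as mean ± SD. The sex and tissue checks, the Lars2 levels of single libraries and values given as CPM of gene reads were not scaled by TMM.

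Genes were named by rule: Prlr; up to 10 rises and 10 falls with the largest change among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups (a condition dropped for averages and differences), passing over predicted genes; up to 4 genes of each list past the threshold, by p; and, where fewer than 5 passed, the 5 genes with the smallest p. The sex and tissue markers were named as checks.

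The 26 gene lists were prolactin and JAK-STAT5 signalling, hormone receptors, nociceptor, myelinated sensory neuron, nerve injury, Schwann and satellite glia, macrophage, cytokine and chemokine, neutrophil, lymphocyte, interferon response, keratinocyte, skeletal muscle, fibroblast and matrix, adipocyte, vascular, erythrocyte, immediate early, cell cycle, circadian clock, glucocorticoid response, translation control, ribosomal protein, RNAs without a poly(A) tail, Y-linked and X-linked genes. A list of mitochondrially encoded genes had no tested member. Lists with at least 3 tested genes went through camera of limma 3.58.1 with its preset correlation of 0.01 and, beside it, with an estimated correlation and through fry. Members were also counted with adjustment over the list alone.

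Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter at 1 CPM in 3 libraries, a fit to the groups compared only, the replicate number as a block, and leaving out each library in turn. A covariate, the mean log2 CPM of the muscle list in each library, and a fit of the female paw without Male paw Veh replicate 2 were chosen after the data were seen. The code was tested on simulated counts with 200 changed genes. At a 2-fold change, recovery was 75.7% in female DRG, 75% in male DRG, 64.4% in female paw and 57.7% in male paw. False calls made up 6.37%, 4.97%, 7.26% and 3.23% of the genes called by edgeR, in the same order. They numbered 10, 8, 9 and 4 in edgeR and 30, 21, 33 and 24 in DESeq2. Gene reads per library ran from 8.99 to 13.3 M in rRNA-depleted DRG, from 6.87 to 13.5 M in rRNA-depleted paw and from 21.8 to 26.5 M in PRL_Sh. Of the reads counted in each file, 36.6% to 38.0% were multimapped in rRNA-depleted DRG and 41.5% to 55.5% in rRNA-depleted paw. A limit for a count of 0 was set at 3 counts over the summed gene reads of an arm. No library was left out of the main comparisons.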

Results

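RNA was measured by sequencing in dorsal root ganglia (DRG), which hold the cell bodies of the sensory neurons, and in hind paw tissue of C57BL/6J mice aged 10 to 12 weeks. The mice had received 1 µg of prolactin (PRL) or vehicle (Veh) into the paw. The 30 libraries fell into 10 groups of 3. Female and male mice each gave a PRL and a Veh group in each tissue, all made by rRNA depletion. Females gave a further group in each tissue, PRL_Sh, whose libraries were made with an mRNA kit. The labels do not say what Sh stands for. The protocol describes a single injection and daily injections over 12 days, and the labels do not assign samples to either. They also do not state that replicates are separate animals, so the p-values measure the spread between these samples. The labels list 18 female and 12 male libraries, while the series text gives 18 males and 12 females. Xist, the RNA that silences an X chromosome, was at 231.1 CPM (normalised counts) or more in every library labelled female and at 6.33 CPM or less in every library labelled male. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 30.3 CPM or more in every male library and at 0.194 CPM or less in every female library.

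Gene reads numbered 8.99 to 13.3 M in the rRNA-depleted DRG libraries and 6.87 to 13.5 M in the rRNA-depleted paw libraries. The PRL_Sh libraries held 22.0 to 26.5 M in DRG and 21.8 to 23.2 M in paw. Male paw Veh replicate 2 had the lowest depth and the lowest share of its reads in genes (13.6%), against 26.2% in the rRNA-depleted paw library with the highest. Among the rRNA-depleted libraries, Scn10a, a sodium channel of pain-sensing neurons, ran from 872.9 to 1224 CPM in DRG and did not exceed 1.73 CPM in paw. In the same libraries Krt10, a keratin of the outer epidermis, ran from 14180 to 28390 CPM in paw and from 3.56 to 40.7 CPM in DRG. Floors given for counts of 0 cover counting error only.

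In the female DRG, prolactin was compared with vehicle to ask which transcripts differ between these arms in sensory ganglia. Wdfy1, an endosomal protein, rose from 30.8 ± 2.08 to 87.2 ± 1.19 CPM (mean ± SD, n = 3; adjusted p = 1.66e-06). Gabra2, a subunit of the GABA-A receptor, rose from 23.2 ± 1.62 to 57.8 ± 1.18 CPM, Nnt, a mitochondrial transhydrogenase, from 20.4 ± 1.58 to 50.7 ± 12.4 CPM, and the pseudogene Tmem181b-ps and the collagen gene Emid2 (Col26a1) by 1.70 and 1.18 on the log2 scale. In PRL_Sh DRG libraries, made with another kit, Wdfy1, Gabra2, Nnt and Tmem181b-ps averaged 27.3, 6.80, 20.2 and 14.35 CPM of gene reads. With Veh these genes averaged 31.1, 23.4, 20.6 and 14.16 CPM of gene reads. A genetic difference between the arms stays open for them, as set out below. Zbtb16, a transcription factor gene induced by glucocorticoids, fell from 98.2 ± 9.99 to 24.3 ± 1.70 CPM (log2 change -2.02 ± 0.18 SE, adjusted p = 0.000238), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, fell from 300.7 ± 11.4 to 154.2 ± 26.5 CPM. Prlr, the prolactin receptor, was at 14.5 ± 2.04 CPM with PRL and 12.9 ± 1.45 CPM with Veh, a difference within the spread (log2 0.17, adjusted p = 0.677). In all, 43 of 14705 genes rose and 53 fell. This balance was not stable, with 113 rises and 58 falls without PRL replicate 3, 10 and 36 without Veh replicate 3, 92 and 61 without Veh replicate 1 and 119 and 89 in DESeq2. All 96 were free of overlap between the libraries of the groups. So were 15.5% of all tested genes, where chance gives 10% for 3 against 3.

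By list, 10 of 13 glucocorticoid-response genes fell in the female DRG (10 adjusted over the list alone; median log2 change -0.96, adjusted p = 0.0986 with an estimated correlation). Of 15 fibroblast and matrix genes 5 rose (11 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation). Of 17 Schwann and satellite glia genes 2 rose (3 rose and 2 fell adjusted over the list alone, adjusted p = 0.637 with an estimated correlation). None of 15 interferon-response genes passed in edgeR (none adjusted over the list alone, adjusted p = 0.637 with an estimated correlation), though all were lower with PRL (log2 change from -1.69 to -0.34), and the Veh libraries differed widely, with a mean log2 CPM of 4.06 ± 1.17 against 3.48 ± 0.12 with PRL. None of 12 neutrophil genes passed either (none adjusted over the list alone; median log2 change 0.89, adjusted p = 0.637 with an estimated correlation). The clock list had 1 fall among 14 genes (4 falls adjusted over the list alone, adjusted p = 0.577 with an estimated correlation). In the prolactin and JAK-STAT5 list 1 of 17 genes rose and 2 fell (1 and 2 adjusted over the list alone). None of 23 nociceptor genes passed edgeR's test (2 falls adjusted over the list alone, adjusted p = 0.637 with an estimated correlation), nor did any of 13 genes of myelinated sensory neurons, 11 hormone receptors or 23 translation-control genes, over all genes or over the list alone. Skeletal muscle transcripts differed widely between libraries, from 0.0250% to 2.76% of gene reads in DRG, with a mean log2 CPM over the muscle list of 6.35 ± 2.65 in female PRL and 3.92 ± 1.01 in female Veh libraries. None of its 17 genes passed over all genes (17 adjusted over the list alone, adjusted p = 0.637 with an estimated correlation). The count of 96 became 38, 28, 20 and 46 without PRL replicate 1, PRL replicate 2, Veh replicate 2 and Veh replicate 3, and 171 and 153 without PRL replicate 3 and Veh replicate 1. It was 34 with only the groups compared, 36 with muscle as a covariate and 208 with DESeq2, and of 28 named genes that passed, 7 kept their call in every alternative (Tmem181b-ps, Wdfy1, Gabra2, Nnt, Emid2, Zbtb16 and Tsc22d3).

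In the male DRG the same question was asked. Wdfy1 rose from 31.1 ± 3.74 to 83.7 ± 2.89 CPM (n = 3, log2 change 1.43 ± 0.08 SE, adjusted p = 3.14e-06) and Gabra2 from 27.0 ± 2.33 to 64.5 ± 5.33 CPM, and Nnt and Emid2 rose by 1.07 and 1.22 on the log2 scale. Agxt2l1 (Etnppl), an enzyme that breaks down phosphoethanolamine, fell from 22.5 ± 2.61 to 3.13 ± 0.72 CPM. Zbtb16 fell from 71.1 ± 19.5 to 16.8 ± 3.68 CPM and Tsc22d3 from 260.3 ± 34.4 to 133.4 ± 19.5 CPM. F3, the tissue factor that starts coagulation, fell by 0.94, Entpd4, a nucleotide-hydrolysing enzyme, by 0.84, and Arid5b, a chromatin regulator, fell by 0.82 on the log2 scale. Prlr was at 14.4 ± 1.60 CPM with PRL and 13.4 ± 2.19 CPM with Veh (log2 0.09, adjusted p = 0.814). In all 42 genes rose and 34 fell, all 76 without overlap between the groups, as for 19.3% of all tested genes. This balance was not stable, with 16 rises and 33 falls without Veh replicate 1, 50 and 23 without Veh replicate 2 and 42 and 21 with only the groups compared.

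Of 13 glucocorticoid-response genes 6 fell in the male DRG (10 adjusted over the list alone; median log2 change -0.63, adjusted p = 0.264 with an estimated correlation). Of 15 fibroblast and matrix genes 5 rose (9 adjusted over the list alone, adjusted p = 0.673 with an estimated correlation). Of 17 Schwann and satellite glia genes 1 rose (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.685 with an estimated correlation). In the clock list 3 of 14 genes rose (3 rose and 4 fell adjusted over the list alone), and camera did not call the list. None of 12 neutrophil genes passed (11 adjusted over the list alone; median log2 change 1.86, adjusted p = 0.685 with an estimated correlation). None of 23 nociceptor genes passed edgeR's test (1 fall adjusted over the list alone, adjusted p = 0.685 with an estimated correlation), nor did any hormone receptor or translation-control gene, over all genes or over the list alone. The muscle list stood at a mean log2 CPM of 6.58 ± 1.17 with PRL and 4.87 ± 2.38 with Veh, with none of 17 genes past the test (none adjusted over the list alone, adjusted p = 0.83 with an estimated correlation). The count of 76 became 36, 31, 44, 49 and 25 without PRL replicates 1, 2 and 3 and Veh replicates 1 and 3. It was 41 with muscle as a covariate and 305 with DESeq2, and of 26 named genes that passed, 11 kept their call in every alternative, among them all those given with CPM above other than Prlr.

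**Figure D1:**
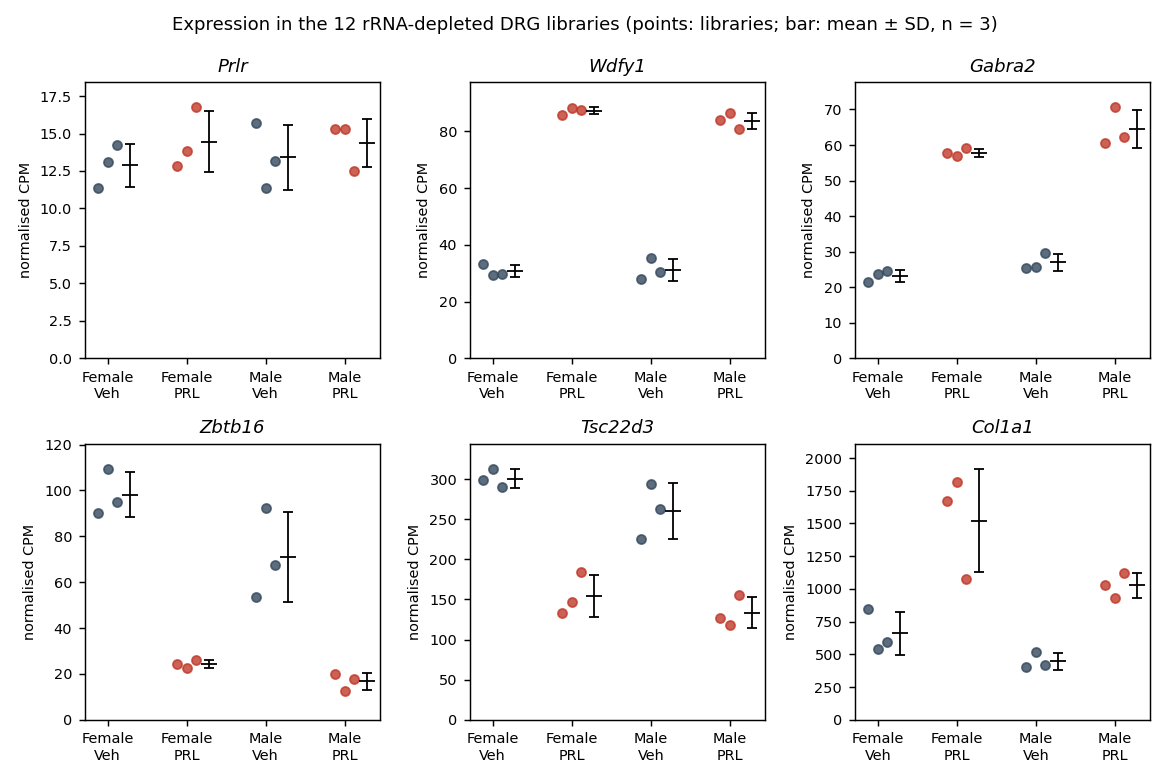
Normalised CPM (vertical axis, starting at 0) of 6 genes in the 12 rRNA-depleted DRG libraries by sex and treatment; points are libraries and bars are mean ± SD (n = 3). Wdfy1 and Gabra2 are higher and Zbtb16 and Tsc22d3 lower in every PRL library than in every Veh library of the same sex, while Prlr overlaps in both sexes.

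The average of the sex-specific changes between PRL and Veh was tested in DRG, which does not require a change in each sex. In this average 314 genes rose and 216 fell. The collagen gene Col1a1 rose from 662.2 ± 165 to 1522 ± 396 CPM in females (n = 3), averaging 445.7 and 1026 CPM in males (log2 change 1.20 ± 0.14 SE, adjusted p = 0.000502). Col3a1 and Col1a2 rose by 1.23 and 0.86 on the log2 scale, Lum and Mmp2, a collagen-binding proteoglycan and a matrix protease, by 0.97 and 0.83, Igf1 by 0.93 and Aplnr, the apelin receptor, by 1.31. Pmp22, a peripheral myelin protein gene, rose by 0.59. Large falls were those of Agxt2l1 (-2.36), Zbtb16 (-2.05), Hif3a, a member of the hypoxia-inducible factor family (-2.02), and the metallothionein gene Mt2 (-1.72). Fkbp5, a chaperone of the glucocorticoid receptor, and the kinase gene Sgk1 fell by 1.05 and 1.22 on the log2 scale.

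Over both sexes 10 of 13 glucocorticoid-response genes fell in DRG (11 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). Of 15 fibroblast and matrix genes 9 rose (11 adjusted over the list alone, adjusted p = 0.445 with an estimated correlation), and of 13 vascular genes 2 rose (4 adjusted over the list alone, adjusted p = 0.511 with an estimated correlation). Schwann and satellite glia genes split into 3 rises and 1 fall of 17 (8 and 2 adjusted over the list alone, adjusted p = 0.594 with an estimated correlation). Of 23 nociceptor genes 1 fell, Mrgpra3, an itch receptor of sensory neurons, from 8.33 ± 0.24 to 5.25 ± 1.14 CPM in females (log2 change over both sexes -0.70, adjusted p = 0.00921; with muscle as a covariate -0.63, adjusted p = 0.0586, highest of its alternatives). Adjusted over the list alone 1 nociceptor gene rose and 7 fell (adjusted p = 0.594 with an estimated correlation). The sexes shared 22 genes higher and 25 lower with PRL, where independent draws would give 0.123 and 0.122, and they share no control libraries. The count of 530 became 305, 276, 847, 992, 271 and 278 without female PRL replicates 1, 2 and 3 and Veh replicates 1, 2 and 3, and 280, 337, 311 and 284 without male PRL replicates 1 and 3 and Veh replicates 1 and 3. It was 189 with muscle as a covariate and 833 with DESeq2, and 25 of 41 named genes that passed kept their call in every alternative.

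Whether females and males differed in their DRG response to PRL was tested as the difference of the sex-specific changes. No gene passed edgeR's test; 537 genes had an unadjusted p under 0.05 and DESeq2 called 1. The smallest p belonged to Nr1d1, a repressor of the circadian clock, at 33.0 ± 4.72 CPM with PRL and 45.6 ± 4.89 CPM with Veh in females and at means of 69.7 and 38.2 CPM in males (n = 3; difference of the log2 changes -1.34, adjusted p = 0.513). Arntl, which drives the clock, had a difference of 1.23 and Prlr of 0.07 (adjusted p = 0.993 for each). In simulated data of this design 65.6% of genes with a 2-fold difference were recovered.

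Between the sexes at baseline, in the Veh DRG, 8 genes differed. Xist, Kdm5c and Kdm6a, X-linked genes that escape or direct X inactivation, were higher in females, Kdm5c at 136.5 ± 7.50 against 86.1 ± 6.28 CPM (n = 3; adjusted p = 0.000672). Ddx3y and Kdm5d were lower by -9.91 and -8.86 on the log2 scale, and Uty and Eif2s3y had no read in the female libraries, against 55.6 ± 5.50 and 41.1 ± 6.86 CPM in males. Gria4, a glutamate receptor subunit, was at 75.8 ± 5.39 CPM in females and 108.8 ± 5.07 CPM in males (log2 -0.52, adjusted p = 0.0295), a call lost in 8 of 13 alternatives, including without any of the 6 libraries in turn. Prlr did not differ detectably (log2 -0.07, adjusted p = 0.924). All 4 Y-linked genes and 3 of 5 X-linked genes passed (4 and 5 adjusted over the list alone), and both lists held with an estimated correlation (adjusted p = 0.000995 and 0.000332); the 16 other lists that camera called did not.

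The female paw, where PRL or vehicle had been injected, was compared to ask which transcripts differ between these arms at the site of injection. Ptprc, the leukocyte surface phosphatase CD45, rose from 38.7 ± 1.89 to 107.5 ± 1.43 CPM (n = 3, log2 change 1.47 ± 0.10 SE, adjusted p = 7.22e-05). Postn, which encodes the matrix protein periostin, rose from 230.7 ± 28.2 to 1407 ± 388 CPM, and Mx1, an interferon-induced antiviral gene, from 2.72 ± 0.68 to 11.4 ± 3.25 CPM. Col6a5, a collagen VI chain, rose from 1.23 ± 0.16 to 171.0 ± 119 CPM, and Mmp12, the macrophage elastase, from 0.764 ± 0.156 to 24.2 ± 11.9 CPM. Fgfbp3, a carrier of fibroblast growth factors, fell from 15.7 ± 2.47 to 3.60 ± 0.87 CPM. Prlr was at 70.9 ± 25.2 CPM with PRL and 94.0 ± 5.40 CPM with Veh (log2 -0.41, adjusted p = 0.24). In all 963 genes rose and 148 fell of 14721, and 1108 of the 1111 were free of overlap between the groups, as for 24.5% of all tested genes. Rises outnumbered falls in every alternative, but by how much was not stable, with 1131 rises and 513 falls with muscle as a covariate, 1127 and 378 without PRL replicate 3, 572 and 35 without Veh replicate 2 and 555 and 42 with only the groups compared.

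Of 16 macrophage genes 15 rose in the female paw (15 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation); Aif1, Emr1 (Adgre1) and Itgam rose by 2.96, 2.07 and 1.41 on the log2 scale. Of 15 interferon-response genes 13 rose (15 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation), among them Irf7 and Bst2 by 1.95 and 1.29. Of 7 lymphocyte genes 4 rose (5 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation): Cd4, Cd2, Cd3e and Lck, each by 2.53 or more. Of 15 matrix genes 9 rose (12 rose and 1 fell adjusted over the list alone, adjusted p = 0.246 with an estimated correlation), with Col3a1 and Col6a1 at 1.80 and 1.62. Of 15 cell-cycle genes 5 rose (13 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation), with Mcm2 and Mcm5 at 0.68 and 0.65. Of 19 cytokine genes 4 rose (8 adjusted over the list alone), Ccl5 among them by 3.39, and camera did not call the list. Of 13 glucocorticoid-response genes 2 fell (7 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation). Among prolactin and JAK-STAT5 genes 3 of 19 rose, Igf1 from 106.7 ± 24.8 to 243.3 ± 16.5 CPM, and 1 fell (4 and 2 adjusted over the list alone). In the list of RNAs without a poly(A) tail 9 of 64 genes rose (11 adjusted over the list alone, adjusted p = 0.398 with an estimated correlation), the histone gene Hist1h1d by 0.76. The neutrophil list split, with 1 rise and 1 fall of 10, Il1r2 at -0.86 (3 and 1 adjusted over the list alone). The muscle list had a mean log2 CPM of 7.94 ± 2.34 with PRL and 9.21 ± 0.99 with Veh, with none of 17 genes past the test (none adjusted over the list alone, adjusted p = 0.661 with an estimated correlation). The count of 1111 became 652, 607 and 579 without PRL replicate 1, Veh replicate 2 and Veh replicate 3, and 597 with only the groups compared. Of 61 named genes that passed, 39 kept their call in every alternative, among them all those given above with CPM except Prlr.

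The male paw was compared in the same way. Ptprc rose from 38.0 ± 2.10 to 124.9 ± 16 CPM (n = 3, log2 change 1.72 ± 0.10 SE, adjusted p = 1.4e-05), Mx1 from 1.42 ± 0.66 to 17.3 ± 4.26 CPM and Postn from 203.3 ± 14.5 to 1347 ± 529 CPM. Irg1 (Acod1), the itaconate-producing enzyme of activated macrophages, rose from 0.789 ± 0.865 to 42.3 ± 13.7 CPM, and Retnla, made by alternatively activated macrophages, from 2.34 ± 0.48 to 122.4 ± 62.7 CPM. Trp63, a master regulator of the epidermis, fell from 399.9 ± 2.11 to 243.1 ± 15.1 CPM, and Tas1r2, a sweet taste receptor subunit, from 7.96 ± 1.11 to 0.153 ± 0.057 CPM. Among single genes, the hair keratin gene Krt34 and the keratin-associated Krtap4-2 fell, by -5.89 and -7.13 on the log2 scale, and Krtap7-1 went from 6.72 ± 2.57 CPM to no read. Prlr was at 50.9 ± 2.15 CPM with PRL and 70.6 ± 2.62 CPM with Veh, without overlap between the groups but not past the threshold (log2 -0.47 ± 0.19 SE, adjusted p = 0.0923). In all 1812 genes rose and 1489 fell, 3271 of the 3301 without overlap, as for 41.5% of all tested genes. This balance was not stable. It was 1353 rises and 1439 falls without Veh replicate 2, 1328 and 1403 without PRL replicate 2, 1553 and 1657 with no filter and 1851 and 1854 in DESeq2.

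Of 16 macrophage genes 14 rose in the male paw (15 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), and all 15 interferon-response genes rose (15 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), with Oasl2 and Cmpk2 at 3.15 and 2.13 on the log2 scale. Of 19 cytokine genes 12 rose (13 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), among them Cxcl10 by 3.90 and Il1b by 3.15. Of 10 neutrophil genes 6 rose, Csf3r by 2.95 (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.489 with an estimated correlation), and of 7 lymphocyte genes 4 rose, Cd4 by 2.83 (5 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Of 15 matrix genes 10 rose (10 adjusted over the list alone, adjusted p = 0.45 with an estimated correlation), Lox, the collagen cross-linking enzyme, by 1.86. Of 17 keratinocyte genes 9 fell (1 rose and 10 fell adjusted over the list alone, adjusted p = 0.36 with an estimated correlation), Col17a1 and Dsp by -0.62 and -0.70. Immediate-early genes fell in 5 of 13 cases (7 adjusted over the list alone, adjusted p = 0.664 with an estimated correlation), Fosb, Egr1 and Dusp1 by -3.33, -1.99 and -1.80. Of 12 adipocyte genes 1 rose and 4 fell, Plin1 by -1.49 (1 and 5 adjusted over the list alone, adjusted p = 0.479 with an estimated correlation), and of 13 glucocorticoid-response genes 6 fell, Errfi1 and Sgk1 by -1.35 and -1.10 (1 rose and 7 fell adjusted over the list alone, adjusted p = 0.479 with an estimated correlation). Clock genes went both ways, 5 up and 6 down of 14 (5 and 6 adjusted over the list alone), Per1 and Arntl at -1.76 and -1.21 and Dbp at 1.31. In the prolactin and JAK-STAT5 list 6 of 19 rose, Igf1 and Jak2 by 1.15 and 0.65, and 3 fell, Myc by -1.03 (8 and 5 adjusted over the list alone). Translation-control genes gave 1 rise and 1 fall of 23, Cpeb1 at 0.87 and Cpeb2 at -0.63 (1 and 1 adjusted over the list alone). Without Male paw Veh replicate 2, the library with the lowest depth, 13 macrophage, 15 interferon and 5 keratinocyte genes still passed in these directions. The muscle list had a mean log2 CPM of 10.6 ± 0.59 with PRL and 9.62 ± 1.26 with Veh. The count of 3301 fell to 2017 without PRL replicate 3, and of 92 named genes that passed, 69 kept their call in every alternative, all of those given above with CPM among them except Prlr.

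**Figure D2:**
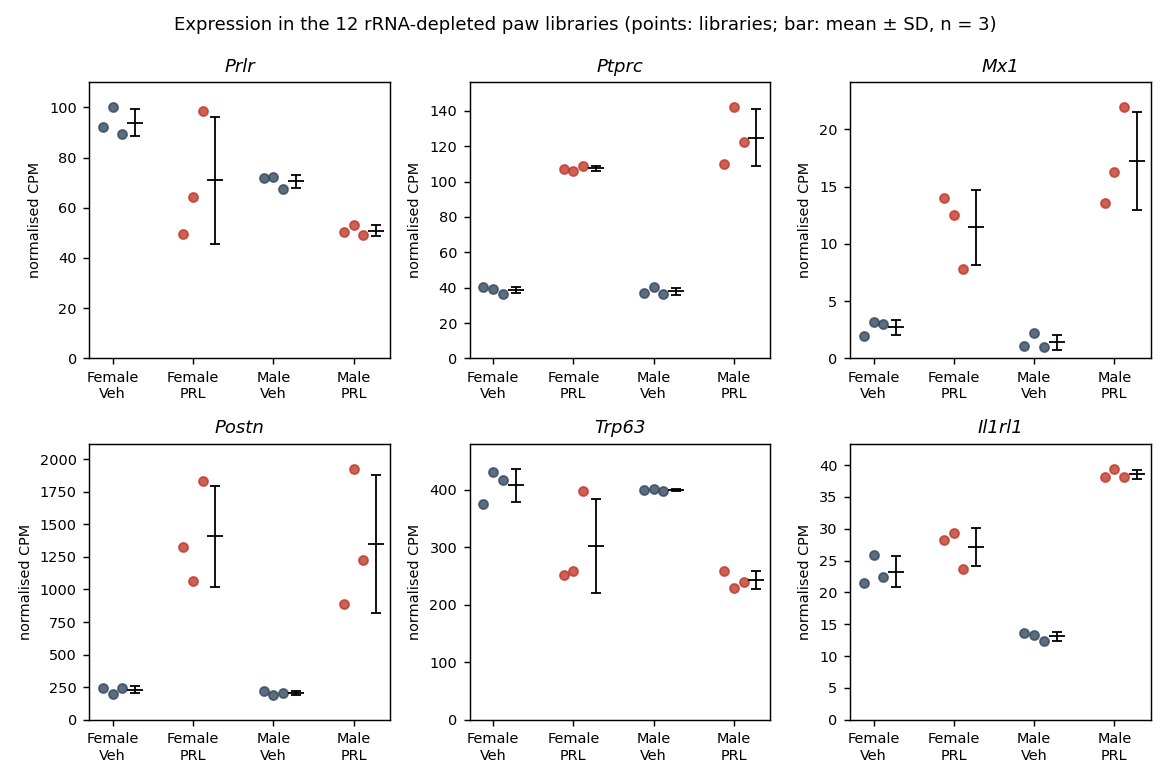
Normalised CPM (vertical axis, starting at 0) of 6 genes in the 12 rRNA-depleted paw libraries by sex and treatment; points are libraries and bars are mean ± SD (n = 3). Ptprc, Mx1 and Postn are higher in every PRL library than in every Veh library of the same sex, Trp63 fell in males from 399.9 to 243.1 CPM, and Prlr overlaps between the groups in females.

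Averaged over the sexes, 2191 genes rose and 1477 fell in the paw. Prlr fell by 0.44 ± 0.13 (SE, log2 scale; adjusted p = 0.0299). That call was lost in 5 of 18 alternatives, with adjusted p = 0.0633 without female PRL replicate 2, 0.0512 and 0.069 without female Veh replicates 1 and 2, 0.0666 without male PRL replicate 3 and 0.0533 without male Veh replicate 1, within a range of 0.000174 to 0.069. Esr1, an oestrogen receptor, rose by 0.70 and Thrb, a thyroid hormone receptor, fell by 0.45 on the log2 scale, and Ret, a receptor for growth factors of the GDNF family, rose by 1.22. All 16 macrophage genes rose (16 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation), as did all 15 interferon-response genes (15 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation) and 11 of 15 matrix genes (13 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). Of 13 vascular genes 4 rose, Vwf and Flt1 by 0.70 and 0.32 (4 rose and 1 fell adjusted over the list alone). Of 72 ribosomal protein genes 1 rose and 5 fell (none adjusted over the list alone, adjusted p = 0.531 with an estimated correlation). The sexes shared 792 genes higher and 95 lower with PRL, where independent draws would give 118.5 and 15.0. Between DRG and paw, 92 genes were higher and 44 lower with PRL in both, where independent draws would give 45.0 and 18.4, while 34 genes higher and 19 lower in DRG were called in the opposite direction in paw. Whether DRG and paw libraries came from the same mice was not tested, and independent draws ignore it. Over all genes the changes in DRG and paw had a Pearson correlation of 0.0052 in females and 0.25 in males. The Spearman correlations were closer to each other, at 0.073 in females and 0.12 in males. Of 99 named genes that passed, 79 kept their call in every alternative.

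**Figure D3:**
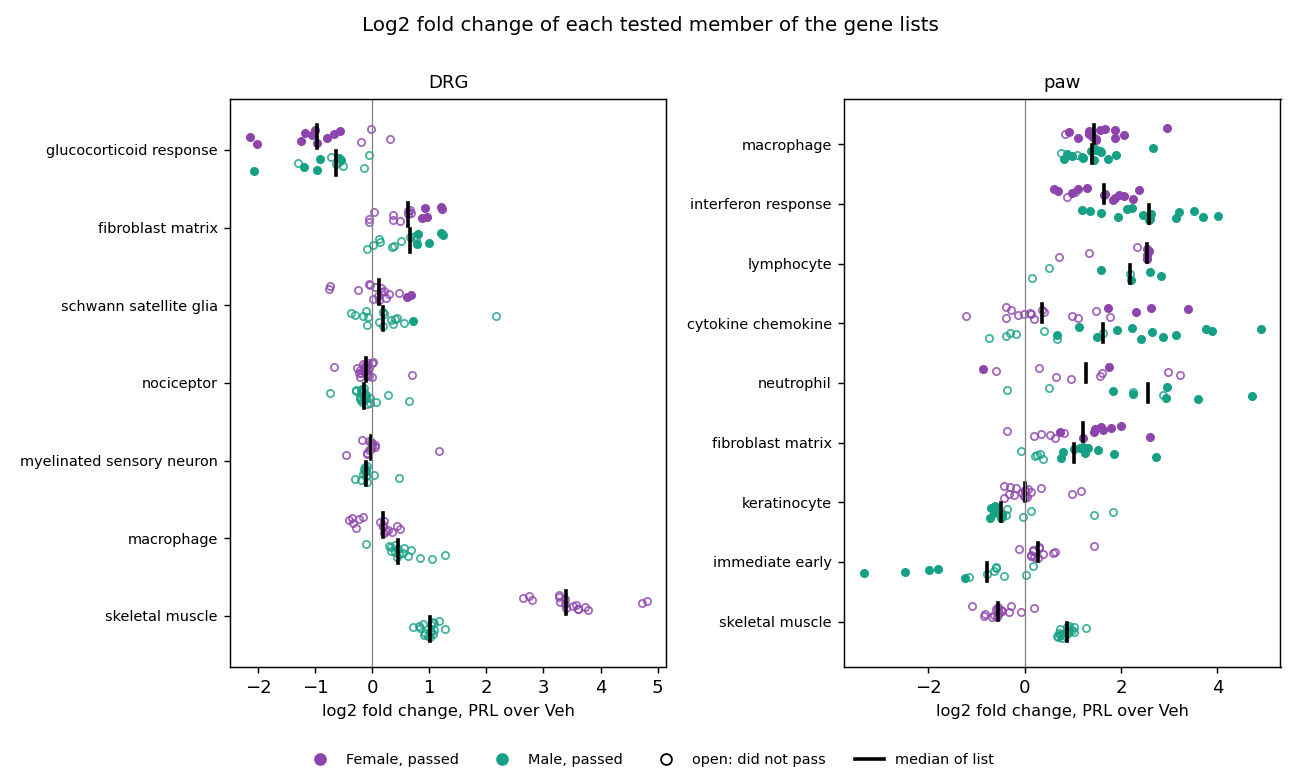
Log2 fold change of PRL over Veh (horizontal axis) for each tested member of gene lists in DRG and paw; filled points passed the test in females or males, open points did not, and black bars are list medians. Glucocorticoid-response genes lie below 0 in DRG with medians of -0.96 in females and -0.63 in males, and macrophage genes above 0 in paw with medians of 1.44 and 1.41.

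Whether the paw response differed between the sexes was tested in the same way as in DRG. Only Il1rl1, the receptor for the cytokine IL-33, passed: it was at 27.1 ± 2.98 CPM with PRL and 23.3 ± 2.36 CPM with Veh in females and at means of 38.6 and 13.1 CPM in males (n = 3; difference of the log2 changes -1.34 ± 0.16 SE, adjusted p = 0.0347 in edgeR). Prlr had a difference of 0.07 (adjusted p = 0.932), and Ccl11, the eosinophil attractant eotaxin, of -1.22 (adjusted p = 0.205). The call of Il1rl1 held without female PRL replicates 1 and 3 (adjusted p = 0.0306 and 0.0417) and was lost without female PRL replicate 2 (0.0591), female Veh replicates 1, 2 and 3 (0.0742, 0.125 and 0.124), male PRL replicates 1, 2 and 3 (0.0627, 0.0969 and 0.0864) and male Veh replicates 1, 2 and 3 (0.108, 0.128 and 0.214). DESeq2 called 158 genes. edgeR called 9 with muscle as a covariate, 6 and 2 without female PRL replicates 1 and 3, and 0 without each of the other 10 libraries. In the test itself 1924 genes had an unadjusted p under 0.05, and simulated data of this design gave 23.8% recovery at a 2-fold difference.

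Between the sexes in the Veh paw 16 genes differed, 6 higher and 10 lower in females. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty kept their call in every alternative. Hal, which degrades histidine in the epidermis, was at 191.7 ± 15.7 CPM in females and 76.6 ± 13.7 CPM in males (n = 3; adjusted p = 0.0161; lost in 5 of 13 alternatives), and Inmt, a methyltransferase, at 6.94 ± 2.59 and 31.5 ± 12.2 CPM (adjusted p = 0.0333; lost in 6 of 13). Il1rl1 was higher in females by 0.83 on the log2 scale (lost in 6 of 13 alternatives), and Crnn, an epidermal envelope gene, was lower by -1.58 (lost in 7 of 13). Prlr was at 94.0 ± 5.40 CPM in females and 70.6 ± 2.62 CPM in males (log2 0.41, adjusted p = 0.605). All 4 Y-linked and 3 of 5 X-linked genes passed (4 and 4 adjusted over the list alone), and both lists held with an estimated correlation (adjusted p = 0.000824 and 0.00419). The count of 16 became 9, 5 and 8 without female Veh replicates 1, 2 and 3 and 10, 5 and 6 without male Veh replicates 1, 2 and 3, and 108 with DESeq2 and 56 with muscle as a covariate.

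Across the 4 comparisons of PRL with Veh by sex and tissue, 11 genes were called in the same direction in all of them, where independent draws would give 0.00105 of the 13550 genes tested in each. Such draws ignore any mice shared between DRG and paw, which was not tested. Wdfy1, Tmem181b-ps, Nnt, Col1a1, Col1a2, Col3a1 and Nid2 rose, and Entpd4, Ide, 8430408G22Rik and LOC100642166 fell. Over all libraries, Wdfy1 ran from 52.5 to 88.4 CPM of gene reads with PRL, from 23.7 to 34.9 CPM with Veh and from 23.5 to 30.3 CPM in PRL_Sh. Nnt ran from 25.4 to 62.5 CPM with PRL, from 9.29 to 22.5 CPM with Veh and from 13.4 to 27.9 CPM in PRL_Sh. LOC100642166, singled out with 8430408G22Rik after its values were seen, had no read in the 12 PRL libraries, a limit of 0.0239 CPM over their summed gene reads, and 15 to 35 reads in each of the 12 Veh libraries and 16 to 35 in each of the 6 PRL_Sh libraries. Of the 11 genes, 6 were called in all 4 comparisons with muscle as a covariate.

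**Figure D4:**
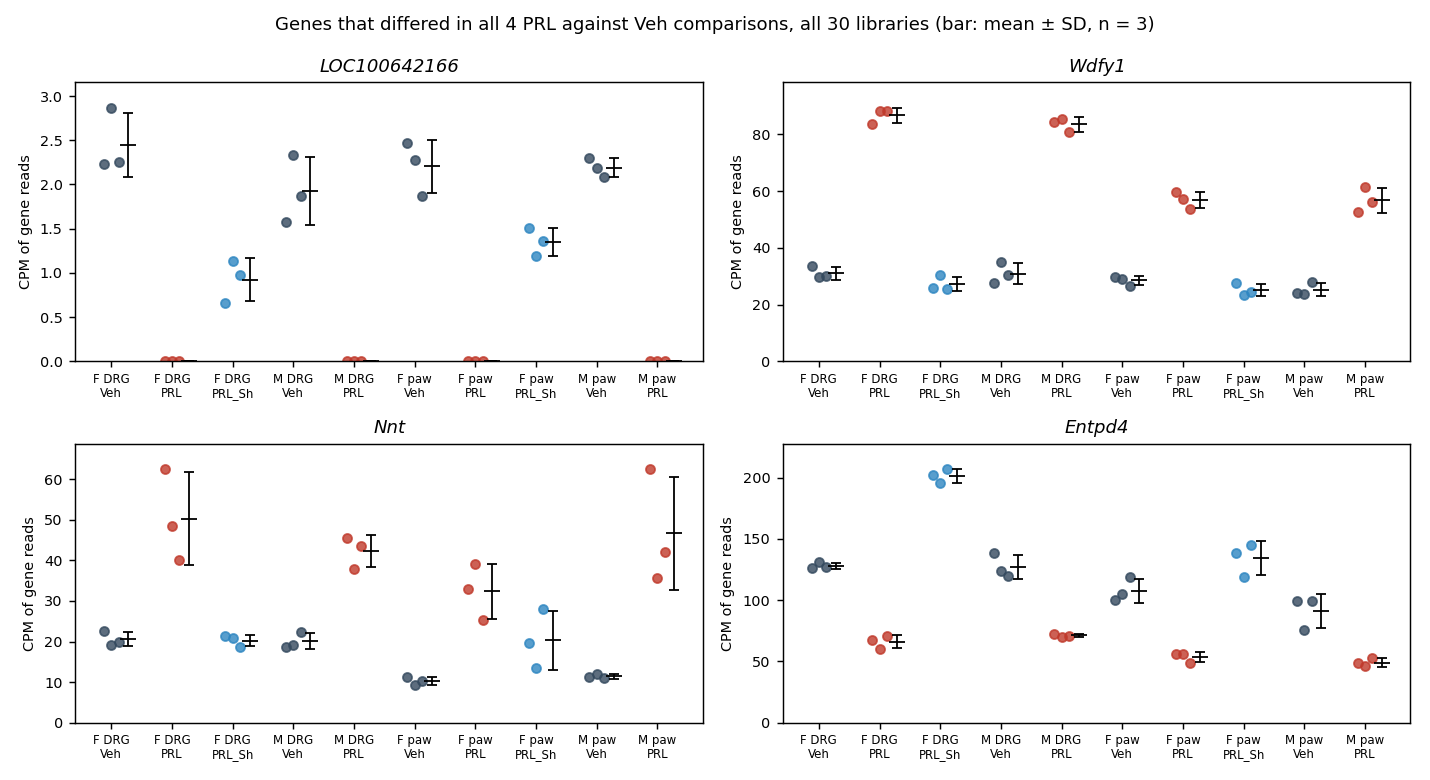
CPM of gene reads (vertical axis, starting at 0) of LOC100642166, Wdfy1, Nnt and Entpd4 in all 30 libraries by sex, tissue and arm; points are libraries and bars are mean ± SD (n = 3). LOC100642166 is at 0 in the 12 PRL libraries and from 0.654 to 2.87 CPM in the others, and Wdfy1 is from 52.5 to 88.4 CPM with PRL and at most 34.9 CPM elsewhere.

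Between PRL_Sh and PRL libraries of the female DRG, RNAs without a poly(A) tail were far lower in PRL_Sh. Rmrp, the RNA of a ribonuclease complex, was at 0.386 ± 0.191 CPM in PRL_Sh and 1294 ± 30.8 CPM in PRL (n = 3; adjusted p = 3.42e-08), and Scarna2, a small Cajal body RNA, had no read against 84.4 ± 4.82 CPM. Of 53 genes of that list 48 were lower and none higher (48 adjusted over the list alone, adjusted p = 0.868 with an estimated correlation). Prlr was at 3.90 ± 0.89 CPM in PRL_Sh and 15.6 ± 2.24 CPM in PRL (log2 -1.99 ± 0.20 SE, adjusted p = 8.66e-05). Of 11 hormone receptor genes 9 were lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.595 with an estimated correlation), with Nr3c1, the glucocorticoid receptor, at -1.63 on the log2 scale. Of 23 nociceptor genes 11 were higher, such as Calca, which encodes the peptide CGRP (0.84), and 3 lower, such as the opioid receptor gene Oprm1 (-4.91); adjusted over the list alone the counts were also 11 and 3. Matrix genes were lower in 13 of 15 cases and higher in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.868 with an estimated correlation), and adipocyte genes lower in 10 of 11 (10 adjusted over the list alone, adjusted p = 0.902 with an estimated correlation). In all 4392 genes were higher and 4843 lower of 14985. Kit and group cannot be told apart here, since all PRL_Sh libraries were made with the mRNA kit and all PRL libraries by rRNA depletion.

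In the female paw 4356 genes were higher and 4297 lower in PRL_Sh than in PRL, with the same tie between kit and group. This balance was not stable, with 4129 higher and 4476 lower under RLE scaling, 3311 and 3535 with the replicate block and 4318 and 4686 in DESeq2. Of 63 genes of RNAs without a poly(A) tail 55 were lower and 4 higher (55 and 4 adjusted over the list alone, adjusted p = 0.39 with an estimated correlation). All 16 macrophage genes were lower (16 adjusted over the list alone, adjusted p = 0.579 with an estimated correlation), Emr1 at 9.56 ± 0.88 CPM in PRL_Sh and 83.1 ± 16.2 CPM in PRL (n = 3), and Mrc1, a mannose receptor, by -4.30 on the log2 scale. Of 15 matrix genes 14 were lower (14 adjusted over the list alone, adjusted p = 0.579 with an estimated correlation), Col3a1 and Fbn1 by -4.47 and -4.52. The acute-phase genes Saa1 and Saa2 were higher by 6.82 and 7.72, and the interferon-induced Isg15 by 2.45, while Prlr was at 34.4 ± 6.27 CPM in PRL_Sh and 73.8 ± 26.2 CPM in PRL (log2 -1.10 ± 0.26 SE, adjusted p = 0.00895). Of 17 muscle genes 9 were higher (9 adjusted over the list alone, adjusted p = 0.816 with an estimated correlation), beside a mean log2 CPM of 11.2 ± 0.49 over the list in PRL_Sh and 8 ± 2.35 in PRL. Of 72 ribosomal protein genes 43 were higher and 7 lower (43 and 7 adjusted over the list alone, adjusted p = 0.7 with an estimated correlation). DRG and paw shared 2299 genes higher and 2662 lower in PRL_Sh, where independent draws would give 1207 and 1332. Of the 11 genes called in all 4 comparisons of PRL with Veh, 9 moved back in PRL_Sh in both tissues, as did 2352 of all 13420 genes (17.5%). These comparisons share the PRL libraries. Simulated PRL_Sh libraries drawn from the PRL means gave 0 genes moved back, but edgeR called 0 genes there in either tissue, so this value does not measure the effect of sharing, and part of the 9 may come from it.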

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

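The tests of the sex difference and of the genes between Fgfbp3 and Ide were set beforehand, and the tests with muscle, clock, macrophage and PRL_Sh values and the regroupings were chosen after the results were seen.

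Across sex and tissue 11 genes moved alike with PRL. A difference in copy number from Fgfbp3 to Ide between the PRL and Veh animals could be a cause for Ide: the median log2 change of 4 tested genes between them was -0.39 over the 4 comparisons, which met the bound set beforehand (below -0.3), with Btaf1 and 4931408D14Rik at -0.39 or lower in each, while in female DRG, male DRG, female paw and male paw Cpeb3 was at -0.05, 0.03, -0.46 and 0.26 and March5 at 0.02, -0.10, -0.19 and -0.15. A stricter reading, that the median of each gene over the 4 comparisons must be below -0.3, was adopted after these values were seen. Cpeb3 and March5 did not meet it. Of 8 genes annotated between Fgfbp3 and Ide only 4 were tested, and they were named after their values were seen. The question stays open. Muscle as a covariate left 6 of the 11 called in all 4 comparisons, which argues against muscle as the whole cause, and in the 5 others the log2 change in female DRG, where all 5 lost their call, stayed near its value with a larger error (8430408G22Rik -1.39 to -1.33, Col1a1 1.20 to 1.08, Col1a2 0.93 to 0.89, Col3a1 1.23 to 1.29, Nid2 0.53 to 0.56). In PRL_Sh, also labelled as PRL, 9 of the 11 moved back in both tissues, and whether through kit or mice cannot be told apart because the kit goes with that group. LOC100642166 had no read in the 12 PRL libraries, but 15 to 35 reads in each Veh and 16 to 35 in each PRL_Sh library. It was read with both kits, so kit alone does not explain its absence with PRL. Prolactin alone would not explain it either if the PRL_Sh mice were treated like the PRL mice, which the labels do not settle. PRL and Veh shared a kit, so for the 11 genes prolactin and a genetic difference between arms stay open. C57BL/6 substrain differences at Nnt, and at Gabra2 outside the 11, are a background possibility not tested here.

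In the paw, 15 of 16 macrophage, 13 of 15 interferon and 9 of 15 matrix genes rose with PRL in females and 14, 15 and 10 in males (adjusted p from 0.105 to 0.45 with an estimated correlation). Over the 26 lists, camera with its preset correlation called 9 in female paw and 10 in male paw. Of those calls fry kept 7 and 8, and an estimated correlation kept 0 in each. A lower share of the other cells would raise markers of every remaining type alike. Macrophage minus vascular mean log2 CPM was apart by at least 1.03 between the lowest PRL and the highest Veh library in each sex. The changes of both lists had been seen when this gap was chosen, so it adds no independent support. It shows only that macrophage genes rose more than vascular genes, and other changes in the mix of cells, such as entry of immune cells, stay open. Without Male paw Veh replicate 2, 13 of 16 macrophage genes were still called in males, which argues against its low gene share as the cause. In PRL_Sh paw libraries, also labelled as PRL, 16 of 16 macrophage genes were lower than in PRL. Group and kit cannot be told apart there because each group had its own kit. An effect of prolactin on immune cells in the paw may underlie the rise and stays open. So do a genetic difference between the arms, the time of collection and the injection schedule, none of which was tested for these genes.

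In DRG, 10 of 13 glucocorticoid-response genes fell with PRL in females and 6 in males (adjusted p = 0.0986 and 0.264 with an estimated correlation). With muscle as a covariate at least 89.4% of the list median was kept in each sex (-0.96 to -0.86 and -0.63 to -0.60; genes past the threshold went from 10 to 7 and from 6 to 4, and the cause of these losses was not tested), which argues against muscle as the whole cause. An evening minus morning score of clock genes differed between PRL and Veh by -0.31 in female DRG, 0.85 in male DRG and 1.67 in male paw without overlap (exact permutation p = 0.1 in each, the smallest possible), and by 0.47 in female paw with overlap (exact permutation p = 0.2). Collection at different times of day may contribute in males, where both tissues shifted alike, but the female tissues shifted in opposite directions, which leaves it open there, and the list medians were negative in both sexes while the DRG scores had opposite signs. A fall in circulating glucocorticoid, a direct effect of prolactin or a genetic difference between the arms was not tested, and each stays open.

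Differences between the sexes in the response to PRL were tested directly. Il1rl1 had a difference (female minus male log2 change) of -1.34 in paw, a call lost without each of 10 of the 12 libraries (adjusted p up to 0.214 in edgeR). In DRG the median difference was -0.42 for macrophage and -0.21 for clock genes. In paw it was -0.80 for cytokine, -0.93 for neutrophil, -0.96 for interferon-response, 0.32 for keratinocyte, -1.40 for muscle, 1.26 for immediate-early, 0.34 for cell-cycle, -0.18 for ribosomal protein genes and 0.24 for RNAs without a poly(A) tail. No member of these lists passed over all genes in edgeR. Adjusted over the list alone, 1 clock gene was higher and 4 lower in DRG, and in paw 5 cytokine, 1 neutrophil and 6 interferon-response genes were lower, 7 immediate-early and 3 cell-cycle genes higher, 12 RNAs without a poly(A) tail higher and 3 lower, and none in the other lists. camera called these 11 lists with its preset correlation and none with an estimated correlation (adjusted p from 0.7 to 0.87).

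Regrouping the libraries tested whether chance can be excluded. For the comparisons of 3 against 3, 1 of 10 splits, the real one, gave as many genes, which is too few splits for a share under 0.05. The real and highest other counts were 96 and 0 (female DRG), 76 and 0 (male DRG), 1111 and 0 (female paw), 3301 and 0 (male paw), 8 and 0 (Veh DRG by sex), 16 and 0 (Veh paw by sex), 9235 and 0 (PRL_Sh DRG) and 8653 and 0 (PRL_Sh paw). For the averages, 1 of 60 splits, the real one, gave as many genes. The real and highest other counts were 530 and 1 in DRG and 3668 and 1145 in paw. These 60 were drawn from 200 distinct splits, and the labels do not state that replicates are separate animals, so chance is not excluded. For the sex difference in paw, 1 gene against 0, 1 of 60 splits gave as many. For that in DRG, 0 genes in edgeR (537 at an unadjusted p under 0.05, 1 in DESeq2) against 1, 60 of 60 did, which a real count of 0 fixes, so it shows nothing.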

How the results depend on the processing

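Muscle as a covariate and the female paw fit without Male paw Veh replicate 2 were chosen after the results were seen. Among 8327 alternative values of named genes, 7562 kept direction and side of the threshold, 747 fell short of it, 9 newly passed it and 9 reversed, all of Prlr where it was not called. Leaving out a library gave 605 of the 747. Over all comparisons camera called 121 lists with its preset correlation, of which 4 held with an estimated correlation and 43 with fry. Fry kept 7 of 9 in female paw, 8 of 10 in male paw, 1 of 14 in female DRG and 1 of 12 in male DRG. Between PRL_Sh and PRL fry kept 5 of 5 in DRG and 4 of 5 in paw, where an estimated correlation kept 0. Unless said otherwise the cause was not tested.

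With DESeq2 the counts moved to 208 (from 96) in female DRG, 305 (76) in male DRG, 833 (530) in averaged DRG, 1 (0) for the sex difference in DRG, 158 (1) for that in paw and 108 (16) between the sexes in Veh paw. In simulated data DESeq2 made more false calls than edgeR in every comparison, such as 19 against 6 for the sex difference in paw. With only the groups compared, which leaves fewer libraries, they moved to 34 in female DRG and 597 (from 1111) in female paw. With muscle as a covariate they were 36, 41 and 189 in female, male and averaged DRG, 9 for the sex difference in paw and 56 between the sexes in Veh paw. RLE scaling, no filter and the 1 CPM filter left every count within 1.5 times. In the fit of the 12 rRNA-depleted DRG libraries the 1 CPM filter removed no tested gene and so tests nothing there. RLE scaling moved no median of all genes by over 0.1 on the log2 scale, and DESeq2 moved only that of PRL_Sh against PRL in female paw by more (0.047 to -0.064).

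Within each tissue the replicate numbers do not pair the libraries as far as values show, since correlations of same-number libraries ran from -0.564 to 0.302. Pairing of DRG with paw libraries was not tested. With the replicate block the sex difference in paw gave 0 genes (from 1; Il1rl1 adjusted p = 0.0792 in edgeR, range over alternatives up to 0.214) and Veh paw between the sexes 8. The other counts, such as 92 in female DRG and 2906 in male paw, stayed within 1.5 times.

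Leaving out each library in turn leaves fewer samples. Counts ran from 20 (Female DRG Veh 2) to 171 (Female DRG PRL 3) in female DRG, 25 (Male DRG Veh 3) to 73 (Male DRG Veh 2) in male DRG, 271 (Female DRG Veh 2) to 992 (Female DRG Veh 1) in averaged DRG, 579 (Female paw Veh 3) to 1505 (Female paw PRL 3) in female paw, 2017 (Male paw PRL 3) to 2792 (Male paw Veh 2) in male paw, 5 (Female paw Veh 2 and Male paw Veh 2) to 10 (Male paw Veh 1) in Veh paw between the sexes, and 0 (10 libraries) to 6 (Female paw PRL 1) for the sex difference in paw. Counts stayed within 1.5 times in averaged paw (2804 to 4368), Veh DRG between the sexes (7 to 7), PRL_Sh DRG (8099 to 8966) and PRL_Sh paw (6986 to 8104), and at 0 for the sex difference in DRG. Without Male paw Veh 2 the female paw count was 1048.

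Prlr reversed where its change was near 0 and not called. Its sex difference in DRG was -0.041 without Female DRG PRL 3, -0.011 without Female DRG Veh 1, -0.017 without Male DRG PRL 3 and -0.061 without Male DRG Veh 1 (range -0.061 to 0.18). Between the sexes in Veh DRG it was 0.014 without Female DRG Veh 1 and 0.070 without Male DRG Veh 1 (range -0.17 to 0.070). In male DRG it was -0.012 without Male DRG Veh 2 (range -0.012 to 0.23). The sex difference in paw was -0.25 with muscle as a covariate and -0.25 without Female paw PRL 3 (range -0.25 to 0.27).

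The spread between libraries and the depth together limit small changes, and depth alone was not varied. In simulated data 1.5-fold changes were recovered in 50% of genes in female DRG, 56.9% in male DRG, 18.1% in female paw and 19.3% in male paw.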

Other observations

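The levels of Lars2 in single libraries were looked up after its change was seen.

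Of 10 tested nerve injury genes none passed edgeR's test in either DRG (1 rise in females and none in males adjusted over the list alone), with adjusted p = 0.637 with an estimated correlation in females. In the male paw 2 of 9 rose and 1 fell (2 and 1 adjusted over the list alone). None of 5 erythrocyte genes in DRG or 3 in paw passed in either sex, over all genes or over the list alone. Of 7 nociceptor-list genes in the female paw 2 rose (2 adjusted over the list alone). In the averaged paw, 14 of 64 genes of RNAs without a poly(A) tail rose (14 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation).

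Lars2, a mitochondrial leucyl-tRNA synthetase, was at 12970 CPM in Male paw Veh replicate 2 and 243.8 CPM in Male paw Veh replicate 3, against 24.4 to 72.1 CPM in the other rRNA-depleted paw libraries. Its averaged change in paw was -3.54 on the log2 scale (adjusted p = 0.0279 in edgeR) and -1.03 without Male paw Veh replicate 2 (adjusted p = 0.134), a call lost in 8 of 17 alternatives. That library also had 55.5% of its reads multimapped.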
